A study of Mus musculus with 7 samples.

How the data were processed

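RNA had been isolated from crude heart mitochondria of mice with a column kit that keeps small RNA, made into libraries with an Illumina small RNA kit and sequenced single end on a MiSeq, per the labels' protocols. There were 3 control libraries (genotype Tefm +/+, with loxP-flanked alleles) and 4 knockout libraries, each taken as 1 mouse since the design text counts mice, and groups and replicate numbers came from the labels. A small RNA kit selects short fragments, so counts at mRNAs and rRNAs come from fragments, and the length range kept is not given in the sources used here.

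The raw counts per gene were made and deposited by the authors, and were whole numbers with a different total in each library. The processing notes of the submitters name genome build mm10, cutadapt 1.10, Bowtie2, SAMtools 1.3.1, bedtools, featureCounts, R 3.3.2 and DESeq2 1.14.1, without saying which step used which. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Counts of near-identical microRNA copies, of overlapping features such as mt-Ti and mt-Tq on opposite strands, and of mitochondrial genes with nuclear copies are therefore uncertain. The normalised signal deposited by the authors was the raw count divided by 1 factor per library, between 0.496 and 2.65, and it was used for checks alone. A table of comparison results deposited by the authors holds a mean normalised signal, a log2 fold change, its standard error and a Wald score, and a p-value with its adjusted p-value, per the file headers. Its log2 fold changes are moderated towards 0, as read from the values.

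Each of 49584 features entered with its deposited identifier and type. For 18 of the 36 mitochondrially encoded features the deposited type contradicted the symbol, and the class was taken from the symbol. Identifiers were matched to GENCODE M21 (GRCm38), where 49289 of 49548 Ensembl identifiers were found, and coordinates are given for the 43712 with the same version. Features that shared a symbol numbered 186 and were kept apart by identifier.

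Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and test with default settings, TMM scaling, 2 groups, no covariate, two-sided) on the raw counts. The default low-count filter, with a minimum count of 10, left 1505 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Normalised counts (CPM) are edgeR's, scaled to normalised library sizes. For genes with 1 to 3 counts in a group a ratio of counts, scaled to normalised library sizes, is given with its exact 95% interval, and no ratio is given where both groups had 3 counts or fewer.

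Positions along the mitochondrial transcripts were compared within each library, as the mean log2(count + 0.5) of promoter-proximal minus distal tRNAs on the H and the L strand and of L-strand minus H-strand tRNAs. These contrasts, and the shares of counts by RNA class, were tested with a two-sided exact permutation test over all 35 splits of the libraries into 3 and 4 (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and Python 3.11.15), whose smallest p is 0.0286. Correlations across genes used 100000 permutations.

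Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01, and again with the estimated correlation and with fry. The lists were H-strand proximal tRNAs, H-strand distal tRNAs, L-strand tRNAs, mitochondrial rRNAs, mitochondrial mRNAs, muscle microRNAs, microRNAs reported to rise and microRNAs reported to fall in cardiac stress, the let-7 family, structural RNAs of cytosol and nucleus, cardiac stress and fetal genes, the mitochondrial integrated stress response, and factors of mitochondrial transcription and RNA processing. Markers of cardiomyocytes, erythroid cells, white blood cells, endothelium, fibroblasts, liver and neural cells were tested alike, and p-values were adjusted over the 18 sets with at least 2 members tested.

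The tests, the gene lists, 16 alternative settings and the rule for named genes were chosen before the data were examined. The rule took Tefm, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap in CPM, up to 4 members of each list with the smallest adjusted p, and the 5 most abundant genes. Of the genes it took, 1 that fell is not reported here, though it stays in the counts. Other members of a list named in the text, and 4 further ratios within libraries, were chosen after the values were seen. The alternatives were other scalings between libraries, other low-count filters, DESeq2 1.42.0, the replicate number as a block, each library left out in turn, another pseudocount (5) and other summaries of the contrasts and shares. A further 14 settings were added after the data were examined, among them a fit with the log2 ratio of microRNA and snoRNA counts to nuclear protein-coding counts as a covariate.

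The procedure was tested on simulated data with the libraries' own means and sizes for 1505 genes. At the fitted dispersion of 0.362, 44.9% of genes changed by 2 log2 units and 88.2% of those changed by 3 were recovered, with 3 false among 133 calls. At the dispersion of nuclear protein-coding genes fitted alone, 0.0755, the shares were 96.3% and 100%, with 0 false among 196 calls. These counts of false calls hold for the simulated data alone. In the real libraries a split that mixed the genotypes called 117 genes, so the simulation does not give the false share there. Figures were drawn with matplotlib 3.10.9.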

Results

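Small RNA sequencing of crude heart mitochondria was compared between 3 control mice and 4 mice in which Tefm had been removed from muscle. Tefm encodes the mitochondrial transcription elongation factor, which binds the mitochondrial RNA polymerase and makes it more processive, and the comparison asked which RNAs of heart mitochondria differ when the factor is missing. Both groups carried Tefm alleles with an exon between loxP sites, and the knockout mice also expressed cre from the muscle creatine kinase promoter, which is active in cardiomyocytes and skeletal muscle. The design text speaks of 4 control mice, of which 3 control libraries were analysed here, and each library was taken as 1 animal. Where this does not hold, p-values measure the spread between libraries alone. Gene counts summed to 1560798, 2570739 and 2015482 in controls 1 to 3 and to 1282873, 1302619, 973835 and 1034099 in knockouts 1 to 4. Of 49584 listed features, 15828 had a count in at least 1 library. Mitochondrially encoded RNAs took between 64.6% of the counts (knockout 4, 95% Wilson interval 64.5 to 64.7) and 88.1% of them (knockout 1, 95% Wilson interval 88.1 to 88.2). The libraries hold short RNAs, so a count for an mRNA or rRNA is a count of its fragments. No molecular identifiers are described, so intervals on counts cover counting error alone.

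The targeted gene itself was at the limit of detection. Tefm (ENSMUSG00000046909.9, chromosome 11, 80136678 to 80142175, minus strand, GRCm38) had 0, 2 and 1 counts in controls 1 to 3 and 0, 1, 0 and 2 counts in knockouts 1 to 4. With 3 counts in each group, a loss of Tefm was not detectable at this depth, and the labels of the libraries could not be checked from it. The loxP sites surround 1 exon, so counts from the rest of the gene would not report the deletion.

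In knockout mitochondria, tRNAs encoded near the start of a mitochondrial transcript were on average high relative to tRNAs encoded farther along it, on both strands. The mitochondrial genome is transcribed from each strand as a long precursor, from which tRNAs, rRNAs and mRNAs are cut. On the heavy (H) strand, the mean log2 count of the 6 promoter-proximal tRNAs (mt-Tf, mt-Tv, mt-Tl1, mt-Ti, mt-Tm and mt-Tw) exceeded that of the 8 distal ones by 0.49 ± 0.28 (SD, n = 3) in controls and by 2.67 ± 0.13 (SD, n = 4) in knockouts. The difference of 2.19 is a 4.55-fold change of proximal over distal tRNAs, and the groups did not overlap (two-sided exact permutation test, p = 0.0286). On the light (L) strand, mt-Tp and mt-Te lay 1.06 log2 units below the 6 distal tRNAs in controls (-1.06 ± 0.30, SD, n = 3) and above them in knockouts (2.51 ± 0.67, SD, n = 4). This was an 11.9-fold change, again without overlap (exact permutation test, p = 0.0286). The balance between the strands, measured as L-strand minus H-strand tRNAs, was -0.25 ± 0.04 in controls and -0.62 ± 0.35 in knockouts (exact permutation test, p = 0.2). These values are taken within a library, so scaling between libraries cancels. The p of 0.0286 is the smallest that 35 splits of 3 and 4 libraries allow, and it became 0.0429 after Benjamini-Hochberg adjustment over the 3 planned contrasts. When counts were summed before taking the log, which gives weight to abundant tRNAs, the H-strand difference was 1.79 (exact permutation test, p = 0.114) and that between strands was -0.86 (p = 0.0286).

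**Figure D1:**
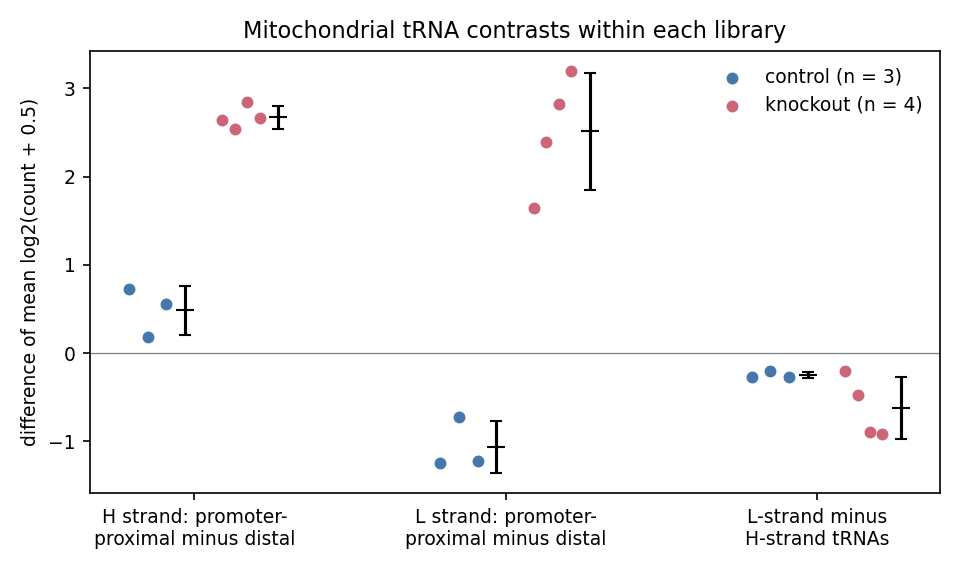
Each point is 1 library and shows the difference of mean log2(count + 0.5) between groups of mitochondrial tRNAs, with the mean and SD of 3 control and 4 knockout libraries beside the points. The proximal minus distal values of all 4 knockout libraries lie above those of all 3 controls on both strands (means 2.67 against 0.49 and 2.51 against -1.06), while the L-strand minus H-strand values overlap.

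Among single mitochondrial genes, 2 tRNAs and the 12S rRNA at the start of the H-strand transcript had positive fold changes and mRNAs had negative ones wherever they lay, and with TMM scaling no rise passed the test over all genes. mt-Tf, the tRNA for phenylalanine and the first gene of the H-strand transcript (chromosome M, 1 to 68, plus strand), was at 566 ± 624 normalised counts (CPM; SD, n = 3) in controls and 10174 ± 6926 (SD, n = 4) in knockouts, a log2 fold change of 4.17 ± 1.15 (SE; edgeR adjusted p = 0.0713), which passed under scaling to total counts or to mitochondrially encoded genes. mt-Tp (15356 to 15422, minus strand), the first tRNA of the L-strand transcript, had 2.69 ± 0.84 (adjusted p = 0.0993), mt-Tv (1025 to 1093) had 2.27 ± 1.1 and mt-Rnr1 (70 to 1024), the 12S rRNA, had 1.27 ± 0.87. mt-7s, the feature for 7S RNA, had 2.27 ± 1.45. The distal tRNA for arginine, mt-Tr (9808 to 9875), fell by 2.20 on the log2 scale (edgeR adjusted p = 0.0461), from 272 ± 33.5 to 59.4 ± 31.7 CPM. Of the 8 H-strand distal tRNAs, 7 had negative fold changes (6 under scaling to mitochondrially encoded genes), among them mt-Tg at -1.77 and mt-Tk at -1.78, which did not pass the test. Within the proximal group mt-Tw was at 1.15 ± 0.93, mt-Tl1 at -1.97 ± 0.92 and mt-Ti at -0.55 ± 0.80, and the abundant mt-Tm was at 0.07 ± 1.04. The high mean of that group thus rests mainly on mt-Tf and mt-Tv. With the composition covariate mt-Tl1 fell (edgeR adjusted p = 0.00246). Of the 8 L-strand tRNAs, 6 were negative (5 under scaling to total counts or to microRNA genes and 4 under scaling to mitochondrially encoded genes), mt-Tn being lowest at -2.42 ± 1.31.

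Fragments of mitochondrial mRNAs were lower in knockouts than in controls. mt-Co1, which encodes subunit 1 of cytochrome c oxidase (chromosome M, 5328 to 6872), fell by 4.09 on the log2 scale (edgeR adjusted p = 0.0377), from 113648 ± 70330 to 6686 ± 2802 CPM (SD, n = 3 and 4). mt-Nd3 (9459 to 9806), a subunit of complex I, fell by 3.13 (adjusted p = 0.0428). All 11 mRNA features had negative fold changes under each of the 6 scalings between libraries. With TMM scaling they ran from -4.09 to -0.16, the latter being mt-Nd6, the mRNA of the L strand. mt-Nd1 had -3.19 ± 0.81 (adjusted p = 0.0566) and mt-Nd4l_4 had -3.15 ± 0.83 (adjusted p = 0.0611). Of the 11, 2 fell over all genes tested and 9 fell when adjusted over the list alone. As a list they ranked low among all genes (median -2.75; camera, adjusted p = 5.05e-05), with adjusted p = 0.945 with an estimated correlation, the members being strongly correlated. By fry, run with all libraries and TMM scaling alone, they passed (down, adjusted p = 0.0471). Of all 36 mitochondrially encoded features, 3 fell and 0 rose over all genes, and 11 passed when adjusted over the list alone. Under scaling to total counts or to mitochondrially encoded genes 2 were called, mt-Tf up and mt-Co1 down, and under scaling to microRNA genes 0. Over all genes DESeq2 called 14, 2 up and 12 down, the composition covariate, chosen after the data were examined, gave 4 up and 18 down, and a fit to mitochondrially encoded genes alone, also chosen afterwards, gave 7 up and 9 down. Leaving out knockout 1 left 1 mitochondrial call, and leaving out any other library left 0. Scaling to total counts put the median log2 fold change of all genes at 0.93, scaling to microRNA genes at 0.68 and scaling to mitochondrially encoded genes at 1.12, against 0.02 here.

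A further 4 ratios within each library were formed after the fold changes were seen, from genes or classes picked in view of them, so they restate those values per library and were not taken as separate tests. H-strand mRNAs relative to mt-Rnr1 went from 1.03 ± 1.63 (SD, n = 3) to -2.72 ± 0.67 (SD, n = 4) on the log2 scale, and mt-Tf relative to H-strand mRNAs from -6.58 ± 2.74 to 0.70 ± 0.43. Mitochondrial mRNAs relative to nuclear protein-coding genes went from 10.81 ± 0.97 to 8.27 ± 0.83, and mt-Tp relative to mt-Nd6 from -0.74 ± 1.70 to 2.59 ± 1.12.

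**Figure D2:**
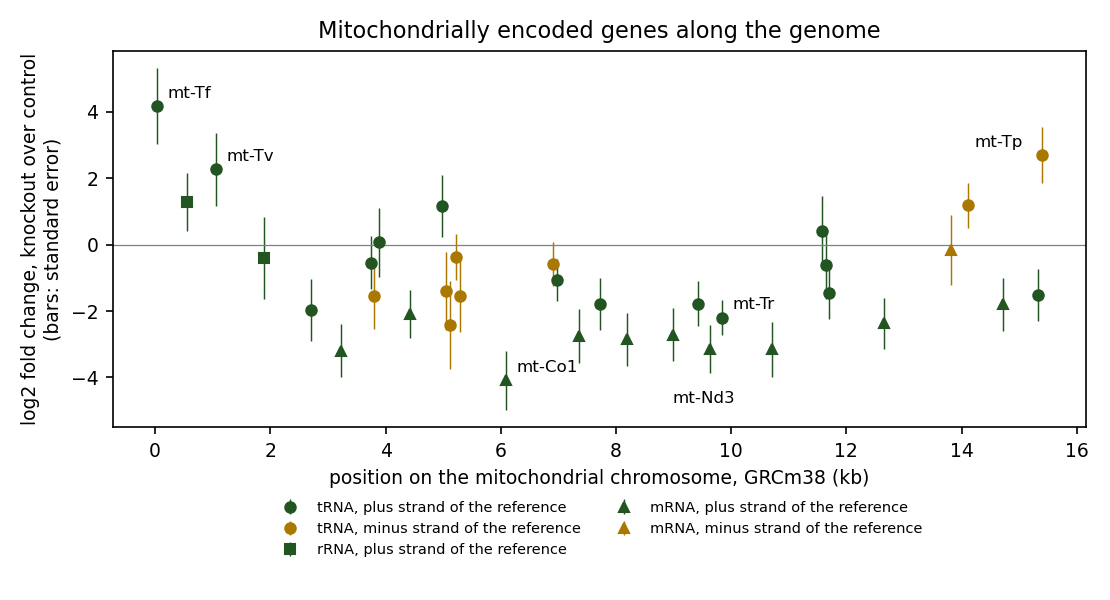
The log2 fold change of each mitochondrially encoded feature with coordinates (knockout over control, bars show the standard error) is plotted against its midpoint on the mitochondrial chromosome of GRCm38 in kilobases, with symbols for tRNA, rRNA and mRNA and colours for the strand of the reference. mt-Tf (4.17) and mt-Tv (2.27) stand at the left end and mt-Tp (2.69) at the right end, and the lowest value is that of mt-Co1 (-4.09).

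The relation of tRNA fold changes to position passed by Pearson's r and not by Spearman's rho on either strand. Across the 14 H-strand tRNAs the fold change was related to position with Pearson r = -0.605 (permutation p = 0.0192, adjusted p = 0.0288 over 3 relations) and Spearman rho = -0.437 (permutation p = 0.118, adjusted p = 0.178). Across the 8 L-strand tRNAs, ordered from their own promoter, r was -0.926 (permutation p = 0.00342, adjusted p = 0.0103) and rho -0.690 (permutation p = 0.0691, adjusted p = 0.178). Without the 2 tRNAs farthest from the median position, r was -0.430 and -0.449, so both relations rest in part on those tRNAs. Across the 10 H-strand mRNAs r was 0.453 (permutation p = 0.189). These relations are across genes, which are not independent replicates. Across libraries, the slope of log2 count on position differed between the groups by -0.253 per kb for H-strand tRNAs, -0.385 per kb for L-strand tRNAs and 0.0775 per kb for H-strand mRNAs (exact permutation test, p = 0.0286 each), all chosen after the fold changes were seen.

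By share of all counts, mitochondrial mRNA fragments made up 40.4% ± 26.8 (SD, n = 3) of control and 8.52% ± 4.54 (SD, n = 4) of knockout libraries (exact permutation test, p = 0.0571). Mitochondrial tRNAs made up 18.8% ± 5.89 and 32.1% ± 8.61 (exact p = 0.114), and 7S RNA 2.95% ± 2.62 and 14.9% ± 9.75 (exact p = 0.114). Mitochondrial rRNA was at 18.8% ± 11.5 and 18.1% ± 7.80, microRNA at 7.32% ± 7.0 and 8.89% ± 7.32, snoRNA at 3.52% ± 4.61 and 4.08% ± 4.24, and nuclear protein-coding RNA at 4.48% ± 1.56 and 7.84% ± 7.28. None of the 9 classes passed after adjustment (lowest exact adjusted p = 0.343). With counts of mitochondrial rRNA left out of the total, the mRNA share differed by -37.0 percentage points (exact permutation test, p = 0.0286). Libraries of both groups also varied in the log2 ratio of microRNA and snoRNA counts to nuclear protein-coding counts, which was 0.71 ± 2.11 (SD, n = 3) in controls and 0.76 ± 2.38 (SD, n = 4) in knockouts (exact permutation test, p = 0.943).

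**Figure D3:**
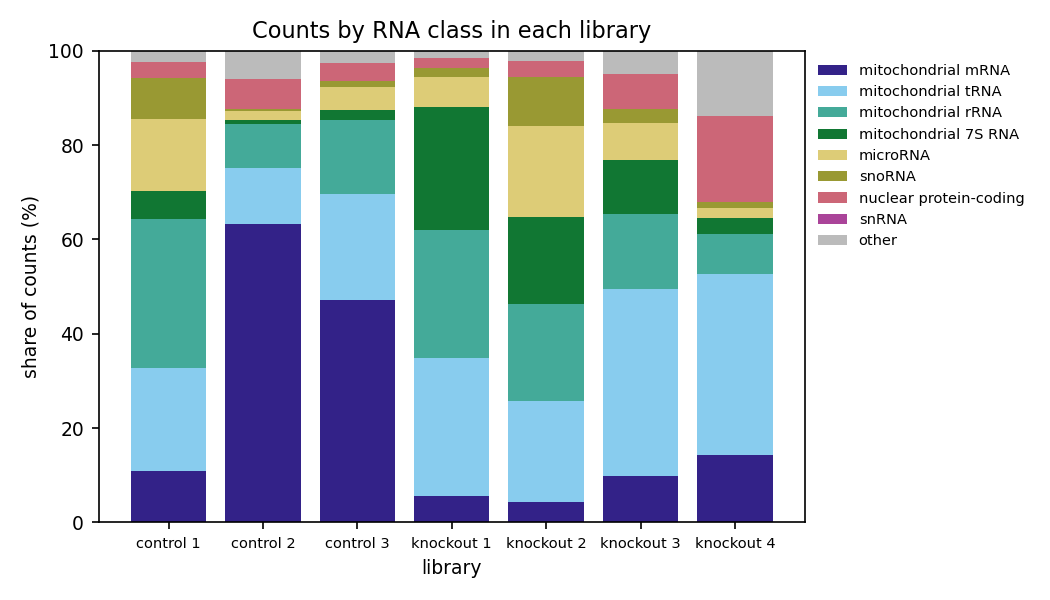
Stacked bars show the percentage of each library's gene counts that falls in each RNA class, for 3 control and 4 knockout libraries. Mitochondrial mRNA takes 40.4% on average in controls and 8.52% in knockouts, and control 1 lies near the knockout libraries in this class.

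Of nuclear protein-coding genes, 79 were higher in knockout libraries, among them Nmrk2, Gdf15, Asns and Myh7, and 23 were lower, among them Hrc. Nmrk2, a muscle nicotinamide riboside kinase, Gdf15, a secreted stress cytokine, and Asns, asparagine synthetase, had the highest rises, with log2 fold changes of 6.01 ± 0.79, 5.92 ± 0.98 and 5.12 ± 0.71 (SE; edgeR adjusted p = 0.00857, 0.0159 and 0.00924). Their control counts were low, so the sizes are uncertain: Nmrk2 had 1 count over 3 controls and 130 over 4 knockouts, a ratio of 103 for equal library sizes (95% counting interval 18.1 to 4087), Gdf15 had 1 and 116 (ratio 91.6, 16.1 to 3651) and Asns had 2 and 110 (ratio 43.5, 11.7 to 363). Myh7, the slow myosin heavy chain that adult mouse ventricle replaces with Myh6, rose from 8.38 ± 4.84 to 214 ± 112 CPM (SD, n = 3 and 4), a log2 fold change of 4.68 ± 0.74 (edgeR adjusted p = 0.0123). Maoa, a monoamine oxidase of the outer mitochondrial membrane, rose by 4.50 ± 0.68 (2 against 65 counts, ratio 25.7, 6.83 to 217; 1 knockout at 18.1 CPM and the others at 7.93 to 9.16), Gars, glycyl-tRNA synthetase, by 3.49 ± 0.37, Aldh18a1, a proline synthesis enzyme, by 3.3 ± 0.49 and Map1a, a microtubule-associated protein, by 3.3 ± 0.60. Of genes that fell, Hrc, a calcium-binding protein of the sarcoplasmic reticulum, went from 90.5 ± 38.8 to 10.8 ± 2.13 CPM (log2 fold change -3.07 ± 0.42, adjusted p = 0.0086). Cd74, the invariant chain of antigen presentation (-2.12 ± 0.43), Fkbp4, a co-chaperone (-2.12 ± 0.43), and Lrtm1 (-2.02 ± 0.29) fell as well. In the same libraries, 12 mRNAs of cytosolic housekeeping genes had a median of 0.35, with 9 positive and 0 past the test (12 positive under scaling to total counts, to microRNA genes or to mitochondrially encoded genes).

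In all, edgeR's quasi-likelihood test called 105 of 1505 genes tested at a Benjamini-Hochberg adjusted p under 0.05, with 79 up and 26 down, of which 102 (79 up and 23 down) were nuclear protein-coding. Under scaling to total counts or to mitochondrially encoded genes 8 were called, 7 up and 1 down, under scaling to microRNA genes 0 (23 at an unadjusted p under 0.05 by edgeR), and DESeq2 called 231, 131 up and 100 down. The count rested on few libraries: it was 0 without control 2 and 0 without control 3 (395 of 2250 and 407 of 2355 genes tested at an unadjusted p under 0.05 by edgeR, against 353 of 1505 with all libraries), 51 without control 1, 25, 30 and 54 without knockouts 2, 3 and 4, and 75 without knockout 1. With the small RNA to protein-coding ratio of each library as a covariate, a fit chosen after the data were examined, 371 genes were called (196 up and 175 down), including all 105. The balance of directions in that fit depended on single libraries, with 167 up and 296 down without control 1 and 119 up and 62 down without knockout 4.

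Of the 15 genes listed for the mitochondrial integrated stress response, 6 had enough counts to test, and 5 of these rose (6 when adjusted over the list alone): Gdf15, Asns and Aldh18a1, Atf4, its transcription factor (2.82 ± 0.60, edgeR adjusted p = 0.0366), and Shmt2, the mitochondrial serine hydroxymethyltransferase (1.97 ± 0.44, adjusted p = 0.0402). Atf5 had 1.47 ± 0.41 (adjusted p = 0.0729). All 6 were low in controls (means from 0.131 CPM for Gdf15 to 2.78 CPM for Atf5), so they passed the low-count filter through the knockouts. A member with such control counts that did not rise could not have entered. The filter thus favoured positive signs, and the count of rises and the rank of the list do not show that the whole list rose. The list ranked high among all genes (median 3.06, with Gdf15 and Asns above it at the lower ends of their intervals too; camera, adjusted p = 3.03e-04), with adjusted p = 0.363 with an estimated correlation. By fry it passed with all libraries (up, adjusted p = 0.0056). Without knockout 2, 3 or 4 the list could not be tested, and without control 2 or control 3, where 0 genes passed, the single genes lost their calls while the list kept its rank.

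Cardiac stress genes had fold changes of both signs, and only rises passed the test over all genes. Of 10 tested, 3 rose: Myh7, Ankrd1, a stretch-responsive cofactor (3.03 ± 0.50, edgeR adjusted p = 0.0159; 34 ± 14.2 to 278 ± 13.4 CPM), and Nppb, the B-type natriuretic peptide (2.71 ± 0.25, adjusted p = 0.00413; 6.03 ± 0.14 to 39.6 ± 3.12 CPM). Acta1, skeletal actin, had 2.12 ± 0.52 (adjusted p = 0.0512) and Nppa 1.76 ± 0.66. These calls ended without control 2 or control 3, where 0 genes passed. Over 29 alternative settings the log2 fold changes were at lowest 4.17 for Myh7, 2.73 for Ankrd1 and 2.51 for Nppb. The other members, all of them genes of contraction or calcium handling in the adult heart, were negative: Atp2a2 at -2.16 ± 0.56, Ryr2 at -1.66 ± 0.47, Actc1 at -1.38 ± 0.49, Pln at -1.35 ± 0.48 and Myh6 at -0.69 ± 0.52, the last being positive under scaling to total counts, to microRNA genes or to mitochondrially encoded genes. Camera and the form of fry given here look for a shift in 1 direction, in which members of opposite sign offset each other. A failure to pass either therefore does not count against changes in both directions. Adjusted over the list alone, 5 rose and 4 fell. As a list they did not pass limma's camera, which ranks them against other genes (adjusted p = 0.625, and adjusted p = 0.945 with an estimated correlation), but passed fry, which asks whether members move on balance in 1 direction (up, adjusted p = 0.0279).

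**Figure D4:**
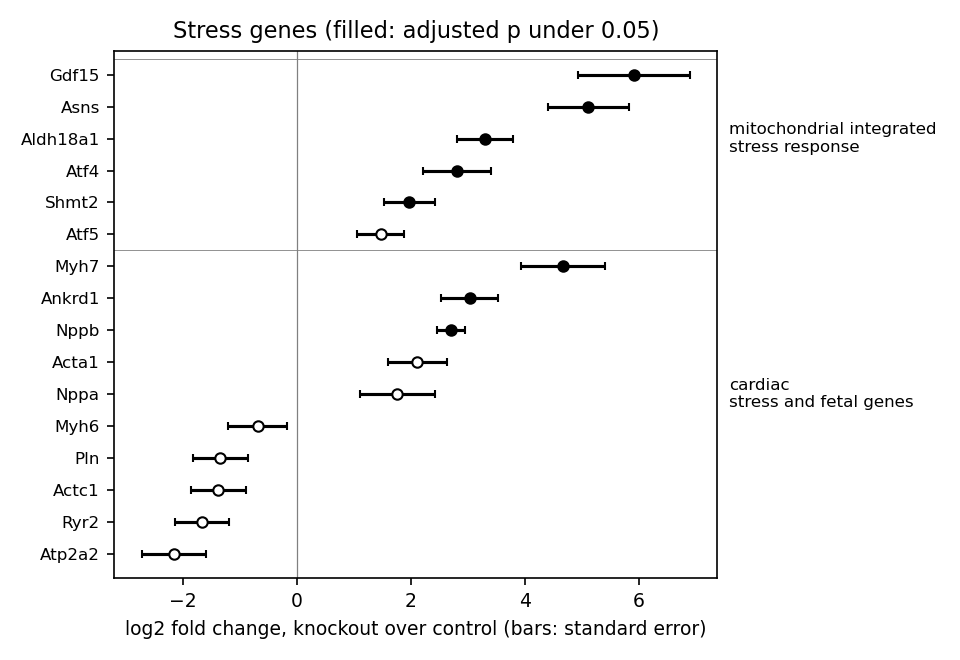
Log2 fold changes (knockout over control, bars show the standard error) of the tested genes of the mitochondrial integrated stress response and of the cardiac stress and fetal gene list, with filled points for an edgeR adjusted p under 0.05. All 6 stress-response genes are positive, also under the other scalings between libraries, while the cardiac list runs from Myh7 (4.68) to Atp2a2 (-2.16). The 6 passed the low-count filter through their knockout counts, which favoured a positive sign.

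All 6 markers of cardiomyocytes had negative fold changes (median -1.03), but 3 of the 6 were positive under scaling to total counts or to mitochondrially encoded genes and 2 under scaling to microRNA genes. Over all genes 0 passed the test, and 3 did when adjusted over the list alone, among them Tnni3, cardiac troponin I (-1.20 ± 0.34), while Mb, myoglobin, had -0.86 ± 0.40. As a set they ranked low by camera (adjusted p = 0.0377), with adjusted p = 0.945 with an estimated correlation. By fry, with TMM scaling, they passed (down, adjusted p = 0.0279). Of the 4 fibroblast markers tested, 1 rose, Postn, a matrix protein of activated fibroblasts (2.69 ± 0.58, edgeR adjusted p = 0.0366), while Col1a1 had 0.67 ± 0.64, Col3a1 0.50 ± 0.60 and Dcn -0.79 ± 0.43. The endothelial markers Cdh5 (-1.11 ± 0.35) and Pecam1 (-0.70 ± 0.43), the white blood cell markers Lyz2 (-0.72 ± 0.29), Mir142 (1.01 ± 1.32) and Mir150 and the erythroid microRNAs Mir451a (0.33 ± 1.16), Mir144 and Mir486 did not pass over all genes, 1 endothelial marker passing when adjusted over the list alone. Camera gave adjusted p = 0.413 for endothelial, 0.73 for white blood cell, 0.91 for erythroid and 0.91 for fibroblast markers. Liver and neural markers had 7 and 0 counts in all libraries together and were not tested.

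MicroRNAs were spread widely within both groups. Of 136 microRNA genes tested, edgeR called 0 (3 at an unadjusted p under 0.05, 0 when adjusted over the list alone) and DESeq2 called 3. The edgeR count was 1 without knockout 4 and 11 with no filter on low counts. Mir208b, which lies within Myh7 (chromosome 14, 54975700 to 54975776, minus strand), was at 38.6 ± 36.0 CPM in controls (SD, n = 3) and 397 ± 422 in knockouts (SD, n = 4), a log2 fold change of 3.36 ± 1.37 (edgeR adjusted p = 0.186). The other tested muscle microRNAs, Mir208a, which lies within Myh6, and Mir499, had 0.30 ± 1.1 and -0.37 ± 1.12, each of them changing sign under other scalings. Of the microRNAs reported to rise in cardiac stress, 9 were tested and 9 were positive (8 under scaling to microRNA genes), led by Mir210 (1.76 ± 1.19) and Mir24-2 (1.53 ± 1.31), with 0 past the test. Of those reported to fall, 8 were tested and 0 passed (Mir150 at -1.18 ± 1.23, Mir29a at 1.0 ± 1.29, Mir30b at 0.79 and Mir26a-2 at 0.62). Of the let-7 family, 10 were tested and 10 were positive (7 under scaling to microRNA genes), from Mirlet7a-1 at 0.38 to Mirlet7c-1 at 1.61, with 0 past the test. Members moved together, with estimated correlations of 0.886 in let-7 and 0.868 among those reported to rise. Their signs are thus not separate observations, and the share positive among all 136 microRNAs is not given here. With the composition covariate, chosen after the data were examined, 24 microRNAs passed, 17 up and 7 down, and Mir208b had 2.85 ± 0.60 (adjusted p = 0.00518). Without control 1 that fit gave 7 up and 15 down, while in each other omission more rose than fell, so the balance rests on control 1.

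The remaining lists did not pass camera with all libraries and TMM scaling. For H-strand distal tRNAs (1 of 8 fell), adjusted p was 0.0588, with adjusted p = 0.945 with an estimated correlation. That list passed, in the same direction, under scaling to total counts (adjusted p = 7.52e-04), to microRNA genes (2.0e-08) or to mitochondrially encoded genes (0.00117), with no filter on low counts (6.30e-09), with the composition covariate (0.0027), without control 2 (0.0304) and without knockout 1 (0.00706). All these used the preset correlation of 0.01, while the estimated correlation of the members was 0.729. By fry the list had adjusted p = 0.3725 with all libraries. With the preset correlation and TMM scaling, splits that mixed the genotypes called up to 8 lists, so these small p-values are weak evidence. Adjusted p was 0.785 for H-strand proximal tRNAs (0 of 6 over all genes, mt-Tf rising when adjusted over the list alone), 0.73 for L-strand tRNAs (0 of 8) and 0.91 for the 2 rRNAs (mt-Rnr2 at -0.40 ± 1.23). It was 0.785 for muscle microRNAs, 0.625 for microRNAs reported to rise, 0.91 for those reported to fall and 0.785 for the let-7 family. Under scaling to microRNA genes, 3 of these lists passed: L-strand tRNAs, low (adjusted p = 4.55e-05), microRNAs reported to rise, high (0.00449), and let-7, high (0.0103). With the estimated correlation, run with all libraries and TMM scaling alone, camera gave adjusted p = 0.945 for each of these 3. With the composition covariate the microRNAs reported to rise passed too (0.0294), and without control 1 and knockout 4, also chosen after the data were examined, so did they (0.00204) and let-7 (0.00225), both high, again with the preset correlation alone. Structural RNAs of cytosol and nucleus, taken as a measure of carry-over into the mitochondrial fraction, had 0 of 10 past the test (adjusted p = 0.91), with Vaultrc5 at 2.83 ± 1.5 (1 knockout at 2862 CPM and the others at 51.4 to 164), Rny1 at 1.58 ± 1.07, Rn7sk at -0.94 ± 0.48 and Malat1 at -0.75 ± 0.57. Of these 10, 4 were positive here, 7 under scaling to total counts and 8 under scaling to mitochondrially encoded genes. For this list the mean (0.11) and the median (-0.13) differed in sign, as did the mean (0.16) and camera's direction for microRNAs reported to fall and the mean (0.0094) and median (-0.0081) of the erythroid markers. Of the 27 factors of mitochondrial transcription and RNA processing, 2 could be tested, Grsf1 (0.92 ± 0.48) and Lrpprc (0.29 ± 0.28), and 0 passed (adjusted p = 0.625).

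The authors' deposited table of DESeq2 results called 197 genes, 112 up and 85 down, among them 14 mitochondrially encoded features (2 up and 12 down) and 1 microRNA. Of the 105 genes called by edgeR, 93 were also called in the authors' deposited table, and all 93 had the same direction. In the authors' deposited table mt-Tf had a log2 fold change of 3.06 (adjusted p = 0.000443), mt-Tp of 2.19 (adjusted p = 0.0068), mt-Co1 of -3.63 (adjusted p = 3e-08) and Mir208b of 2.04 (adjusted p = 0.113).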

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

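The tests of explanations and of other splits in this part were chosen after the results were seen. In the knockout libraries 3 of 76 values examined had 1 library far from the others, against 3.8 that chance alone gives at 1 in 20, and 2 of them are given here. In 1 library Maoa was at 18.1 normalised CPM, with the other knockouts between 7.93 and 9.16. For Vaultrc5, a vault RNA, 1 library was at 2862 normalised CPM against 51.4 to 164. The control group of 3 libraries was not examined in this way.

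The shift of mitochondrial RNA towards promoter-proximal tRNAs was weighed against technical explanations. With the composition ratio of each library in a linear model, the H-strand difference was 2.18 ± 0.163 (SE), beyond the SD of the controls. The group means of that ratio differed by only 0.0480, so the adjustment could hardly move the difference. Their balance argues against a linear effect of the microRNA and snoRNA to protein-coding ratio as its cause, and does not bear on composition within mitochondrial RNA. With tRNA length (59 to 75 bases) and strand in a model of 22 tRNAs per library, the effect of a promoter-proximal position differed between the groups by 2.97 (larger SD 0.264; 2.61 without length), which argues against length as the whole cause, though the slope on length differed too (-0.231 per base, exact permutation p = 0.0286) and a part in the pattern stays open. Fragmentation common to a whole library stays open: the difference of -2.54 between mitochondrial mRNAs and nuclear protein-coding genes was known from the fold changes and does not bear on tRNAs. Reduced elongation by the mitochondrial RNA polymerase without Tefm may underlie the shift, a hypothesis that, like altered RNA stability or processing, was not tested separately. Some values run against a loss that grows with distance. The slope for H-strand mRNAs differed the other way (0.0775 per kb), promoter-proximal mt-Tl1 was at -1.97 ± 0.92 and distal mt-Th at 0.40 ± 1.06.

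The rise and fall of nuclear genes was weighed against carry-over and cell type. A lower share of cardiomyocytes, with the other cell types kept in proportion, would raise the markers of those types alike. Cdh5 was at -1.11 ± 0.355 and Lyz2 was also negative by more than 2 standard errors, while Postn was positive by more than 2. This argues against that form of it as the whole cause. Both endothelial markers were positive under scaling to mitochondrially encoded genes, which moves all markers alike and so leaves the gap between them. Postn marks activated fibroblasts, and a lower share of cardiomyocytes together with changes in the other cell types stays open. More cytosolic mRNA in knockout preparations would raise housekeeping mRNAs, of which 12 of 101 listed were tested. Their median was 0.345 ± 0.156 (bootstrap SE over the 12 genes), with 9 positive and 0 called (12 positive and a median of 1.20 under scaling to total counts). That SE treats genes as replicates and does not measure the spread between mice. The median lies between the bounds set for either outcome. Nuclear protein-coding genes were 1235 of the 1505 tested, and TMM scaling put the median of all genes at 0.02, so it would remove much of a rise common to them. A contribution of cytosolic mRNA and a response of the heart therefore cannot be told apart.

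The ratio of microRNA and snoRNA to nuclear protein-coding counts differed widely between libraries of the same group. It was 2.88, -1.35 and 0.61 in controls 1 to 3 and 1.84, 3.11, 0.54 and -2.44 in knockouts 1 to 4, and the group means differed by 0.0480 with SDs of 2.11 and 2.38, which argues against genotype as its source. The 3 highest values were those of control 1 and knockouts 1 and 2, labelled S1 to S3 in the column headers. Whether that numbering marks an order of processing or a batch is not given, so a batch stays open. Sequencing depth was related to it with r = -0.180 (exact permutation p = 0.724; rho = 0.143), but with r = 0.755 without the 2 libraries farthest in depth, so depth stays open. The share of counts at Gm42418, a locus that overlaps ribosomal RNA repeats, followed it (r = -0.879, exact permutation p = 0.00238, adjusted p = 0.00476 over 2 relations; rho = -0.893; r = -0.699 without the 2 farthest libraries). That share also went with the share of nuclear protein-coding counts, the denominator of the ratio. Both were lowest in knockout 1 (1.01% and 2.28%) and highest in knockout 4 (13.0% and 18.2%). The relation thus does not show that reads from ribosomal RNA repeats moved the ratio, and what made it vary was not tested.

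Chance could not be excluded for the count of 105 genes called: another split of the libraries gave 117, and 2 of the 35 splits gave at least 105. That split set controls 2 and 3 and knockouts 3 and 4 against the rest, called 44 microRNAs, and gave 2 genes once composition was a covariate. The rest, control 1 and knockouts 1 and 2, are the samples labelled S1 to S3 in the column headers, and had the 3 highest composition ratios. The split thus follows both composition and that numbering. Nor could it be excluded for the 2 lists called (highest other split 8, with more lists than the real split in 26 splits and as many in 32 of 35, the real one included), and for microRNAs nothing can be said, since with 0 called all 35 splits give as many by construction (highest other 44). For the 3 mitochondrially encoded genes the real split alone gave as many (1 of 35, highest other 0). With the composition covariate so it did for all genes (371, highest other 94), mitochondrially encoded genes (22, highest other 12) and microRNAs (24, highest other 0). The same held for nuclear protein-coding genes fitted alone (262, highest other 52). A share of 1 of 35 is the smallest the splits allow and was not adjusted over the counts examined. The covariate and the fit to 1 class were chosen after the data were seen, so these counts make chance less likely without excluding it.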

How the results depend on the processing

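The covariate, the fits to 1 class of genes, the 2-library omission, the robust and the newer edgeR fits were tests chosen after the results were seen, while the other settings were planned. Of 1256 values of 59 named genes, 1014 kept direction and side of the threshold, 133 lost the call, 76 gained it and 33 changed sign. For lists taken 1 by 1 these numbers were 210, 2, 15 and 17 of 244, and for named genes with the covariate and a library left out 339, 41, 6 and 6 of 392. Both planned proximal minus distal contrasts stayed positive in each alternative. Depth limits Tefm, whose fitted log2 fold change with no filter was -0.38 (edgeR adjusted p = 0.942), and the stress-response list, which could not be tested without knockout 2, 3 or 4. Exact tests with a library left out were not run. Except where fewer libraries or genes enter, the cause was not tested.

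Genes called numbered 105. They were 8 under scaling to total counts, 8 under scaling to mitochondrially encoded genes, 0 under scaling to microRNA genes (edgeR, 23 at an unadjusted p under 0.05, 231 by DESeq2 with its own scaling), 192 with no filter, 231 with DESeq2, 371 with the composition covariate, 380 with the covariate and scaling outside mitochondrial DNA, and 262 among nuclear protein-coding genes alone. Leaving out 1 library gave 0 to 75, with 0 without control 2 or control 3, and 181 (without knockout 4) to 463 (without control 1) with the covariate. Mitochondrially encoded genes called numbered 3, all down: they were 2 (1 up) under scaling to total counts or to mitochondrially encoded genes, 0 under scaling to microRNA genes, 1 with no filter, 14 with DESeq2 (2 up), 22 with the covariate (4 up), 21 with the covariate and scaling outside mitochondrial DNA (3 up), 16 when fitted alone (7 up), 8 without control 1 and knockout 4 (1 up), 1 with the robust and 5 with the newer fit, 0 to 1 with 1 library left out, and 9 (without knockout 3) to 27 (without knockout 1) with the covariate. MicroRNAs called numbered 0: they were 1 under scaling to total counts or to mitochondrially encoded genes, 11 with no filter, 3 with DESeq2, 24 with the covariate, with either scaling, 4 without control 1 and knockout 4, 0 to 1 with 1 library left out and 14 to 23 with the covariate. Lists called numbered 2: they were 6 under scaling to microRNA genes, 4 with the covariate, 4 without control 1 and knockout 4, 0 with the estimated correlation, and 1 to 3 with 1 library left out.

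Replicate numbers are not stated to pair the libraries. The deviations of same-numbered libraries correlated at 0.53, -0.80 and 0.32, which does not settle whether animals were paired, by these numbers or otherwise. With the replicate block 0 genes and 0 mitochondrially encoded genes were called (338 at an unadjusted p under 0.05 by edgeR), Mir499 was at 0.0076 and mt-Tm at -0.31. The direction by camera turned from low to high for structural RNAs (mean log2 fold change 0.32) and for microRNAs reported to fall (mean 0.70). MicroRNAs reported to rise passed with the preset correlation (camera, adjusted p = 0.0373), while the estimated correlation, run without the block, gave adjusted p = 0.945 for them.

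For lists, the change was in the direction of the set test (camera or fry), and the numbers given are means of log2 fold changes, whose sign can differ from that direction. With all libraries, camera's direction was low for structural RNAs (mean 0.11) and microRNAs reported to fall (mean 0.16) and high for let-7 and mitochondrial rRNAs. It turned for the structural RNA list, with means of 0.69 under scaling to total counts, 0.78 under scaling to mitochondrially encoded genes, 1.0 without control 1 and knockout 4, 0.11 by fry (the same mean, direction up), and, over all omissions, -0.35 to 0.78 with 1 library left out. It turned in some omissions too for microRNAs reported to fall (mean 1.83 without control 1 and knockout 4, -0.82 to 1.27 with 1 left out), let-7 (-0.12 to 2.02) and mitochondrial rRNAs (0.10 under scaling to microRNA genes, -0.22 to 0.92 with 1 left out). For single genes, log2 fold changes that changed sign were as follows. Without control 1 and knockout 4, mt-Rnr2 was at 0.82, Mir499 at 0.99, Mir150 at 0.91 and mt-Tm at -0.31. With 1 library left out the ranges were -1.22 to 0.31 for mt-Rnr2, -1.27 to 0.48 for Mir499, -0.50 to 1.06 for Mir208a, -1.88 to 0.40 for Mir150, -0.11 to 1.76 for Mir30b, -0.0564 to 1.41 for Mir26a-2, -0.0083 to 3.40 for Vaultrc5 and -0.50 to 0.91 for mt-Tm. With the covariate as well they were -0.64 to 0.20 for Mir208a, -0.17 to 0.62 for Mir30b, -0.11 to 0.81 for Mirlet7i and -0.81 to 0.77 for mt-Tm. Mir208a was at -0.22 under scaling to microRNA genes, -0.13 with the covariate and -0.16 with the covariate and scaling outside mitochondrial DNA. For mt-Tm the values were -0.0081 with RLE scaling, -0.0032 with no filter, -0.0081 with DESeq2, -0.0695 with the covariate and -0.10 with the covariate and scaling outside mitochondrial DNA. Malat1 was at 0.54, 0.40 and 0.77 under scaling to total counts, microRNA genes and mitochondrially encoded genes, and under the last Rn7sk was at 0.0144 and Mir499 at 0.0171.

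From summed counts the H-strand contrast was 1.79 (exact permutation p = 0.114), and L-strand minus H-strand tRNAs differed by -1.03 with medians and -0.86 with summed counts (exact permutation p = 0.0286 each). The share of mitochondrial mRNA differed by -37.0 points outside mitochondrial rRNA and -36.8 with mt-Rnr2 left out, where that of mitochondrial rRNA differed by 3.16 (exact permutation p = 0.0286 each).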

Other observations

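All tests in this part were chosen after the results were seen, and the genes named here after their values were seen. Of 8 cytosolic aminoacyl-tRNA synthetases tested, which charge tRNAs for cytosolic translation, 8 were positive under each of the 6 scalings and 6 rose (edgeR, adjusted over all genes), among them Sars (2.89 ± 0.27), Iars (2.72 ± 0.37), Nars (2.58 ± 0.44), Aars (1.53 ± 0.34) and Eprs (1.51 ± 0.35). Yars (1.36 ± 0.53) and Lars (2.10 ± 0.66) did not pass. Single genes that rose included Gyg, glycogenin, at 2.25 ± 0.32, Gbe1, the branching enzyme, at 2.16 ± 0.29, Pgm2 at 1.84 ± 0.27 and Ugp2 at 1.58 ± 0.34. Others were Tgfb2, a growth factor, at 3.18 ± 0.72, Lox, which cross-links collagen, at 2.59 ± 0.43 and Ctgf at 2.48 ± 0.52. Lonp1, a mitochondrial protease, rose by 2.09 ± 0.31, Sqstm1, an autophagy receptor, by 2.06 ± 0.38 and Txnrd1, a thioredoxin reductase, by 2.73 ± 0.43. These calls, like the 105 as a whole, ended without control 2 or control 3.

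Among genes that fell were Ivd (-1.92 ± 0.38), Ech1 (-1.74 ± 0.36), Eci1 (-1.53 ± 0.33) and Cpt2 (-1.35 ± 0.30), of mitochondrial fatty acid and branched-chain amino acid oxidation, where 4 of 18 tested fell and 14 were negative (6 under scaling to total counts, 9 to microRNA genes and 5 to mitochondrially encoded genes). Of 21 subunits of the respiratory chain encoded in the nucleus, 1 fell, Cox7a1 (-1.60 ± 0.35), and 20 were negative with a median of -0.53 (1 negative under scaling to total counts, 5 to microRNA genes and 1 to mitochondrially encoded genes). The calls of these single genes ended without control 2 or control 3 too.

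Whether these groups move beyond their noticed members was tested with camera on members not noticed first. Synthetases may rise as a group, but p was 0.00228 with the preset correlation and p = 0.0768 with an estimated correlation (4 tested, 2 up). For fatty acid and branched-chain amino acid oxidation p was 0.00139 and 0.193 (16 tested, 2 down). For the respiratory chain p was 2.52e-06 and 0.0834, but there no member was set aside and Cox7a1 was among the 21 tested. Each of these 3 hypotheses stays open.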
